A study of Mus musculus with 18 samples.

How the data were processed

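RNA from RAW264.7 cells was converted to poly(A)-selected, strand-specific libraries, per the labels' protocols, for 18 samples in 6 groups of 3. The labels do not say whether samples of a group came from separate cultures. The submitters' processing notes name FastQC 0.11.5, STAR 2.5.3a, featureCounts, edgeR and Cuffdiff 2.2.1 without giving the role of each, and the authors' genome build and annotation are not given in the sources used here, so no coordinates are printed. The deposited table is the output of the authors' Cuffdiff comparisons, per the file headers and name. Each row names 2 groups and gives the fold change as a linear ratio by the authors, its direction, the FPKM (fragment counts scaled by transcript length and library size) of the deposited pair of groups as 1 total, and a deposited q-value, which is a p-value the authors adjusted for multiple tests. How the authors scaled FPKM between libraries and over which tests they adjusted q are not given in the sources used here.

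The deposited table has 112230 rows. Of these, 77406 rows name a group outside the 6 groups of the samples used here and were not used, which left 34824 rows over 15 pairs of groups. In these rows the smallest fold was 2, the largest q 0.0499 and the smallest summed FPKM 0.550, so the table had been filtered, and 71.8% of rows carried the same smallest q of 3.9e-04. It lists no infinite fold, so a gene at 0 in a group cannot appear in a comparison with that group. Many abundant genes, such as Actb and Gapdh, have no row in any comparison used here. The lower level of a pair was rebuilt as the total divided by 1 plus the fold, and the higher as that value times the fold. This reads the total as a sum, on which the absolute FPKM rest and the ratios do not. Levels rebuilt from different comparisons were averaged by the median, and 17763 repeated levels of at least 1 FPKM differed by a median of 0.0652%. A rebuilt level is the authors' value for a group and has no SD.

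Of the 7315 entries used, 6956 have a transcript identifier and 359 a locus identifier. Of the transcript identifiers 6900 were found in GENCODE M21, 6767 with the same gene name (an exact match of symbols), and biotypes were taken from there. Entries without a gene name (255) or with more than 1 (36) were left out of gene counts. A gene counts as higher or lower if all its called entries go that way, and its printed value is that of the called entry with the highest summed FPKM, which can be a minor transcript. The 7 comparisons, the gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. The design had foreseen tests on values per sample; as the table has none, the calls are the authors' at a q of 0.05 or less, and no test of a single gene or of an interaction was run.

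There were 31 gene lists with 616 distinct genes. As the table lists only called genes, each list with at least 3 called members was tested by asking whether its called members split between higher and lower as the other called genes did (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over the 50 tests made). Of these, 18 had an adjusted p of 0.05 or less and 32 did not. This does not ask whether a list holds more called genes than others, and counts adjusted over the list alone could not be made without unadjusted p-values. As a description, a list's median log2 ratio of rebuilt levels was placed among 10000 random lists of the same size drawn from the listed genes and matched on mean level in 10 bins. The text names Cited1, then per comparison the 10 largest rises and falls by deposited fold among called genes with at least 1 FPKM in one of both groups. It further names the 4 most changed called members of each list with at least 3 called, with up to 3 more where a list leads, and members of a list of interferon signalling genes. Results that rest on some genes are not given here, so fewer list tests are printed than were made. Symbols of predicted genes (Gm numbers, Rik names) were passed over. Overlaps were counted only between comparisons that share no group.

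Alternatives were a q of 0.01 or less, a minimum of 1 FPKM, a pseudocount of 1 with at least 1.5-fold, and rescaling to a median log2 ratio of 0 over entries of at least 1 FPKM in one of both groups. Another 2, leaving out pseudogenes and counting entries, were added after the data were examined. The rebuilding of levels, the counting of calls and the list test were tested on simulated data. These held 4000 genes for interferon-gamma against no treatment in construct cells, with 200 genes changed. The changes were a log2 change of 1.5 or 3 in either direction. All 100% of the changed genes were recovered with their sign and 0 unchanged genes were called. This follows from the setting, since simulated rows had no replicates and were called at 2-fold, and it does not test the authors' calls. Of random lists 3.40% had a Fisher's exact p of 0.05 or less. A simulated list of genes that all rose lay at percentile 94.2 of random lists, since the random lists too are drawn from changed genes. Computations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.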

Results

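Poly(A)-selected RNA was sequenced from RAW264.7 cells, a mouse macrophage-like cell line, in 6 groups of 3 samples. Parental cells were untreated or given doxycycline at 100 ng/mL. The other 4 groups were RAW264.7 cells that carry a lentiviral construct from which doxycycline induces mouse CITED1, a transcriptional co-regulator without a DNA-binding domain of its own. These construct cells were untreated, given doxycycline, given interferon-gamma at 200 U/mL, or given both. The values come from the authors' deposited table of pairwise comparisons, which holds 1 fold change, 1 summed FPKM and 1 q-value per row and no values per sample. No SD, no n and no sequencing depth can therefore be attached to a value, and every call is the authors' own. The rows between these 6 groups covered 7315 transcript or locus entries from 5455 named genes. All listed changes were at least 2-fold with a q of 0.05 or less, so a gene with no row is not shown to be unchanged. Levels are FPKM rebuilt from the fold and the summed FPKM, and where a group's level of at least 1 FPKM could be rebuilt from several comparisons the results differed by at most 0.756%.

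**Figure D1:**
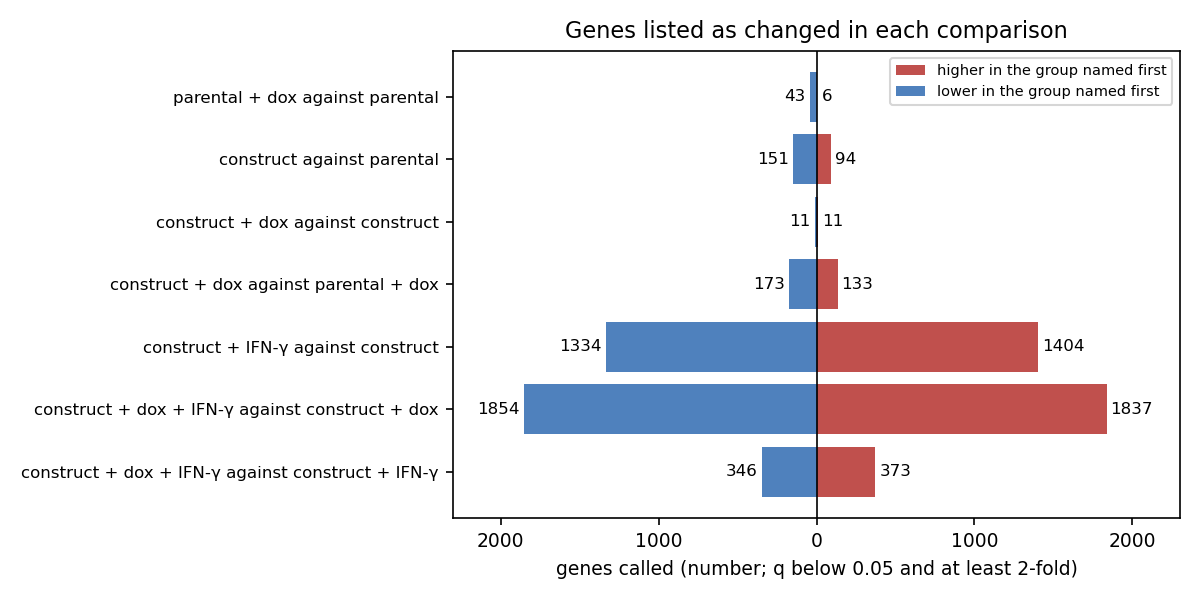
Number of genes called higher (right) or lower (left) in the group named first, for the 7 comparisons, from the authors' deposited table; bars start at 0. Doxycycline alone gave 6 genes higher and 43 lower in parental cells, and interferon-gamma with doxycycline gave 1837 higher and 1854 lower in construct cells.

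The induced gene was examined first. Cited1 (entry ENSMUST00000050551) rose 239-fold with doxycycline in unstimulated construct cells in the authors' deposited table, from a rebuilt FPKM of 0.703 to 168. Interferon-gamma without doxycycline also raised Cited1, 16.3-fold by the authors' deposited table, to a rebuilt FPKM of 11.5. With both treatments its rebuilt FPKM was 86.7, which was 7.55-fold above interferon-gamma alone in the authors' deposited table. The level with both treatments lay below that with doxycycline alone, but this difference was under the 2-fold limit of the table and has no row. Cited1 has no row in any comparison with a parental group, so its parental level is not given here.

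Doxycycline in parental cells, which controls for the inducer itself, was followed by few calls, and most concerned pseudogenes. Of 49 genes called, 6 were higher and 43 lower, and 34 of the 43 lower entries are annotated as pseudogenes. The largest falls were Rpl19-ps11, from 75.4 to 19.7 rebuilt FPKM, and Rps6-ps4, from 46.9 to 14.2, both pseudogenes of ribosomal protein genes. Other pseudogenes among the 10 largest falls were Rps15-ps2, Rps15a-ps7, Rpl17-ps3, Rpl9-ps6, Sms-ps, Impdh2-ps and Pcna-ps2, a copy of the replication clamp gene. Rps27rt, a retrogene of a ribosomal protein gene, went from 62.3 to 25.8 rebuilt FPKM. Among the genes that were higher, 4 with an assigned symbol reached 1 FPKM in one of both groups: Rin3, a Rab5 exchange factor, at 3.97-fold in the authors' deposited table, with St18, Brat1 and the helicase gene Wrn. No gene list had 3 called members. Reads from a pseudogene and its parent gene can be shared, so these levels are uncertain. At a q of 0.01 or less 25 genes were called, all lower, and without pseudogene entries, an alternative chosen after the data were examined, 14 genes.

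Construct cells without inducer were compared with untreated parental cells, which covers transduction, selection and any leak of the construct. In all, 94 genes were higher and 151 lower by the authors' deposited table. Osteoclast-associated genes were higher: tartrate-resistant acid phosphatase Acp5 went from 0.428 to 2.43 rebuilt FPKM, the osteoclast transcription factor Nfatc1 from 1.60 to 8.49, the proton pump subunit Atp6v0d2 from 3.22 to 10.9 and the fusion receptor Dcstamp from 10.3 to 20.7. All 4 called members of that list were higher, a split that did not pass the test against the other called genes (Fisher's exact test, two-sided, adjusted p = 0.0548). Angptl2, a secreted angiopoietin-like protein, was 22.4-fold higher and the nuclear factor Tox2 18.8-fold higher in the authors' deposited table. Further large rises were Gpr179, Palm, Slc16a12, Zfp467, Emp2 and the homeobox gene Rhox5, which went from 1.57 to 11.3 rebuilt FPKM. Among the falls, the T-cell costimulatory receptor gene Cd28 went from 4.06 to 0.115 rebuilt FPKM and the RNA-binding protein gene Igf2bp1 from 1.01 to 0.0154. Tmem176b and Tmem176a, neighbouring genes for membrane proteins of myeloid cells, fell from 41.6 to 3.28 and from 12.6 to 1.02 rebuilt FPKM. Cd84, Psma8, Svil, Rtl8b, Mreg and the protease inhibitor gene Slpi completed the 10 largest falls. Of the cytokine and chemokine list 1 member was higher and 4 lower, among them Il1rn (74.8 to 30.9 rebuilt FPKM) and Ccl4 (208 to 90.6), and this split did not pass the test (Fisher's exact test, two-sided, adjusted p = 0.80). Pseudogenes made up 28 of the 163 lower entries.

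With doxycycline in both lines the construct cells again differed from parental cells, with 133 genes higher and 173 lower in the authors' deposited table. All 6 called osteoclast-list members were higher (Fisher's exact test, two-sided, adjusted p = 0.0186), led by Acp5 (0.473 to 4.27 rebuilt FPKM), the integrin gene Itgb3 (0.0758 to 0.564), Ocstamp (0.0912 to 0.539) and Atp6v0d2 (2.83 to 14.0). That call is lost when genes below 1 FPKM in both groups are left out (Fisher's exact test, adjusted p = 0.0791), which removes Itgb3 and Ocstamp. Tox2, Angptl2, the BH3-only gene Bmf and the inhibitory receptor gene Pdcd1 were the largest rises, at 22.2-fold, 19.2-fold, 14.3-fold and 13.8-fold in the authors' deposited table. Igf2bp1, Svil, Cytip, Cd84, Cd28, Dkk2, the macrophage elastase gene Mmp12, Cpeb1, Psma8 and Rtl8b were the largest falls. Of the cytokine list 1 member was higher and 5 were lower, with Tnf at 27.0 and 13.3 rebuilt FPKM and the chemokine gene Ccl5, the member that was higher, at 3.92 and 8.18 (Fisher's exact test, two-sided, adjusted p = 0.417). Of the pattern recognition list 3 members were lower, namely Tlr8, Clec4e and Nlrc4 (Fisher's exact test, two-sided, adjusted p = 0.420). The M2-type list went both ways, with Egr2 and Klf4 higher and Tgm2 and Myc lower (Fisher's exact test, two-sided, adjusted p = 1). The comparisons of construct with parental cells, without and with doxycycline, share no group. They had 61 genes higher in both and 99 lower in both, where lists drawn independently from the 5455 listed genes would share 2.29 and 4.79, and 0 genes were called in opposite directions.

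Induction of CITED1 in unstimulated cells was followed by 22 called genes, 11 higher and 11 lower. After Cited1 itself, the largest rise was in Pde1b, a calcium- and calmodulin-dependent phosphodiesterase, from 1.73 to 9.55 rebuilt FPKM. The aminoacylase gene Acy1 went from 2.91 to 7.55 rebuilt FPKM, and Itgal, the alpha chain of the integrin LFA-1, from 1.15 to 2.54. Aoc2, Champ1 and the phospholipase gene Pla1a were the other rises of genes with an assigned symbol that reached 1 FPKM in one of both groups. Among the falls were Rbak at 2.74-fold, the neutrophil chemokine gene Cxcl2 at 2.5-fold and the fatty acid binding protein gene Fabp4 at 2.29-fold in the authors' deposited table. Lims2, Eps8, Rgcc, the lymphatic growth factor gene Vegfc and the peptidylarginine deiminase gene Padi2 were also lower. No gene of the antiviral list was called. At a q of 0.01 or less 13 genes were called. With a pseudocount of 1 FPKM, of the genes named here Cited1, Pde1b, Acy1 and Fabp4 stayed at least 2-fold apart and the others did not. No gene was called in both this comparison and doxycycline in parental cells. Independent lists of these sizes would share only 0.0121 genes higher and 0.0867 lower, so this overlap cannot show that the inducer had no part. Whether the inducer acted differently in the 2 lines was not tested.

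Interferon-gamma without doxycycline changed a large part of the transcriptome of construct cells. There were 1404 genes higher, 1334 lower and 10 with entries in both directions in the authors' deposited table. The largest rise was Gbp5, an interferon-inducible GTPase, from 0.108 to 217 rebuilt FPKM. The dendritic-cell lectin gene Clec9a went from 0.0437 to 80.4 rebuilt FPKM, the chemokine gene Ccl22 from 0.0648 to 71.2, and Socs1, a feedback inhibitor of JAK signalling, from 0.203 to 95.9. Gbp10, Upp1, Slamf8, the transcription factor gene Batf2, complement factor B (Cfb) and the argininosuccinate synthase gene Ass1 completed the 10 largest rises. The mTOR-binding protein gene Deptor fell 119-fold and the fractalkine receptor gene Cx3cr1 fell 36.3-fold in the authors' deposited table. Igf1, Cldn11, Cd33, Zfp658, Ctsk, Fabp4, Igfbp4 and Tmem158 were the other large falls.

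Genes of interferon signalling were higher with interferon-gamma alone, among them Stat2 from 10.0 to 114 rebuilt FPKM, Cd274, the gene of PD-L1, from 1.78 to 203 and Socs3 from 3.78 to 48.8. Jak1, Jak2, Stat3, Irf2, Irf9, Nlrc5, Fcgr1, Fcgr4, Socs1 and Batf2 were also higher. Ciita has no row in this comparison, and Irf1, Irf8, Ifngr1, Ifngr2, Cxcl9, Cxcl10, Cxcl11, Icam1, Nos2, Ido1, Acod1, Wars and Tap1 have none in any comparison used here. The antiviral list had 33 members higher and 0 lower (Fisher's exact test, two-sided, adjusted p = 1.3e-08), with Mx1 from 0.0919 to 14.1 rebuilt FPKM, Zbp1 from 2.77 to 102, Ifit1 from 1.68 to 59.6 and Isg15 from 17.1 to 358. All 10 called members of the MHC class I and immunoproteasome list were higher (Fisher's exact test, two-sided, adjusted p = 0.0066), led by Tapbpl (2.66 to 45.5 rebuilt FPKM), Nlrc5, H2-T10 and H2-Q7. The 5 called GTPase genes, Gbp5, Gbp10, Gbp7, Gbp3 and Gvin1, were all higher, a split that did not pass the test (Fisher's exact test, two-sided, adjusted p = 0.137).

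Inflammatory lists rose too. All 15 called members of the NF-kB list were higher (Fisher's exact test, two-sided, adjusted p = 4.5e-04), with the costimulatory receptor gene Cd40 from 1.26 to 81.3 rebuilt FPKM, Bcl2a1a from 1.55 to 45.0, Nfkbiz from 1.28 to 13.9 and Traf1 from 1.95 to 20.8. All 9 called cytokine and chemokine genes were higher (Fisher's exact test, two-sided, adjusted p = 0.0123), with Tnf from 15.4 to 189 rebuilt FPKM, Il15 from 1.67 to 23.1, Lif from 0.0286 to 2.66 and the antagonist gene Il1rn from 30.9 to 205. The 8 called immediate early genes were higher (Fisher's exact test, two-sided, adjusted p = 0.0219), led by Egr1, Fosl1, Egr3 and the phosphatase gene Dusp1. Pattern recognition genes had 9 members higher, such as Tlr9, Casp4, Clec7a and Casp1, and 2 lower, Tlr2 and Tlr7, and did not pass the test (Fisher's exact test, two-sided, adjusted p = 0.137).

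Cell cycle genes fell with interferon-gamma. Of the list 23 members were lower and 2 higher (Fisher's exact test, two-sided, adjusted p = 6.4e-05), with cyclin A2 (Ccna2) from 92.8 to 20.8 rebuilt FPKM, Cenpf from 9.92 to 2.2, thymidine kinase (Tk1) from 59.2 to 13.5 and cyclin B2 (Ccnb2) from 67.7 to 16.0. Cdkn1a, the gene of the cell cycle inhibitor p21, was one of the members that were higher, from 123 to 487 rebuilt FPKM. These list tests ask only whether called members split between higher and lower as the other called genes do, and members of a list are not independent of each other. With levels rescaled so that listed genes had a median log2 ratio of 0, a shift of 0.65, 33.7% of the calls were higher in place of 51.3%. Of the entries with both levels 4.90% had a log2 ratio within 0.5 of 0, so that median falls between the changed genes of either direction.

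Interferon-gamma in cells with induced CITED1 was followed by 1837 genes higher, 1854 lower and 8 with entries in both directions, by the authors' deposited table. Slamf8 rose from 0.148 to 204 rebuilt FPKM, the chemokine receptor gene Xcr1 from 0.0360 to 17.7, Ccl22 from 0.171 to 80.3 and Cfb from 0.640 to 261. Socs1, Ass1, Ifit3b, Ms4a4c, Ifi209 and Phf11a were the other large rises. The tight junction gene Cldn11 fell 342-fold, Igfbp4 fell 243-fold and the sphingosine phosphate receptor gene S1pr1 fell 238-fold in the authors' deposited table. Igf1, Cd33, Xrcc5, Dhrs3, Cx3cr1, Rab3il1 and Trem2, a receptor of lipid-handling macrophages, were also among the 10 largest falls. The antiviral list had 29 members higher and 0 lower (Fisher's exact test, two-sided, adjusted p = 3.6e-08), with Ifit3 from 1.71 to 296 rebuilt FPKM, Isg15 from 19.0 to 1429 and Isg20 from 2.2 to 139. The main entries of several members, such as Usp18, Cmpk2 and Ifi44, have no row for the group with both treatments. Counts of called members therefore cannot be compared between comparisons with and without that group. Also higher throughout were the called members of the NF-kB list (15 members, Fisher's exact test, adjusted p = 2.3e-04), the cytokine list (12, adjusted p = 0.0011), the immediate early list (12, adjusted p = 0.0011) and the MHC class I list (9, adjusted p = 0.0066). Of the pattern recognition list 13 members were higher and 1 lower (Fisher's exact test, two-sided, adjusted p = 0.0035), with Casp4 from 5.09 to 94.0 rebuilt FPKM, Tlr9 from 6.12 to 113 and Tlr3 from 1.72 to 28.2. All 23 called cell cycle genes were lower (Fisher's exact test, two-sided, adjusted p = 3.7e-06), led by Tk1, Cenpf, Bub1b and Ccna2. The main entry of Cdkn1a has no row for the group with both treatments, so whether its rise was kept there is not known. With rescaled levels, a shift of 1.02, 28.0% of the calls were higher in place of 49.8%.

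In interferon-gamma-stimulated cells the induction of CITED1 was followed by 373 genes higher and 346 lower, by the authors' deposited table. The antiviral list rose again: 22 members were higher and 0 lower (Fisher's exact test, two-sided, adjusted p = 5.8e-06). Ifit3b, of a family of RNA-binding antiviral proteins, went from 8.21 with interferon-gamma alone to 131 rebuilt FPKM with both treatments. Ifit3 went from 54.5 to 296 rebuilt FPKM, Mx1 from 14.1 to 69.6, the ubiquitin-like modifier gene Isg15 from 358 to 1429, and Ifnb1, the gene of interferon-beta, from 1.40 to 6.18. The value of Ifit1, from 2.10 to 10.7 rebuilt FPKM, is that of a minor entry, since its main entry has no row for the group with both treatments. All 13 called members of the cytokine and chemokine list were higher (Fisher's exact test, two-sided, adjusted p = 0.0011). Il10, a cytokine that dampens macrophage activation, went from 0.222 to 1.82 rebuilt FPKM, Csf1 from 2.10 to 8.64, Il1b from 0.918 to 3.34, Il6 from 1.37 to 3.96 and Il27 from 113 to 292.

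**Figure D2:**
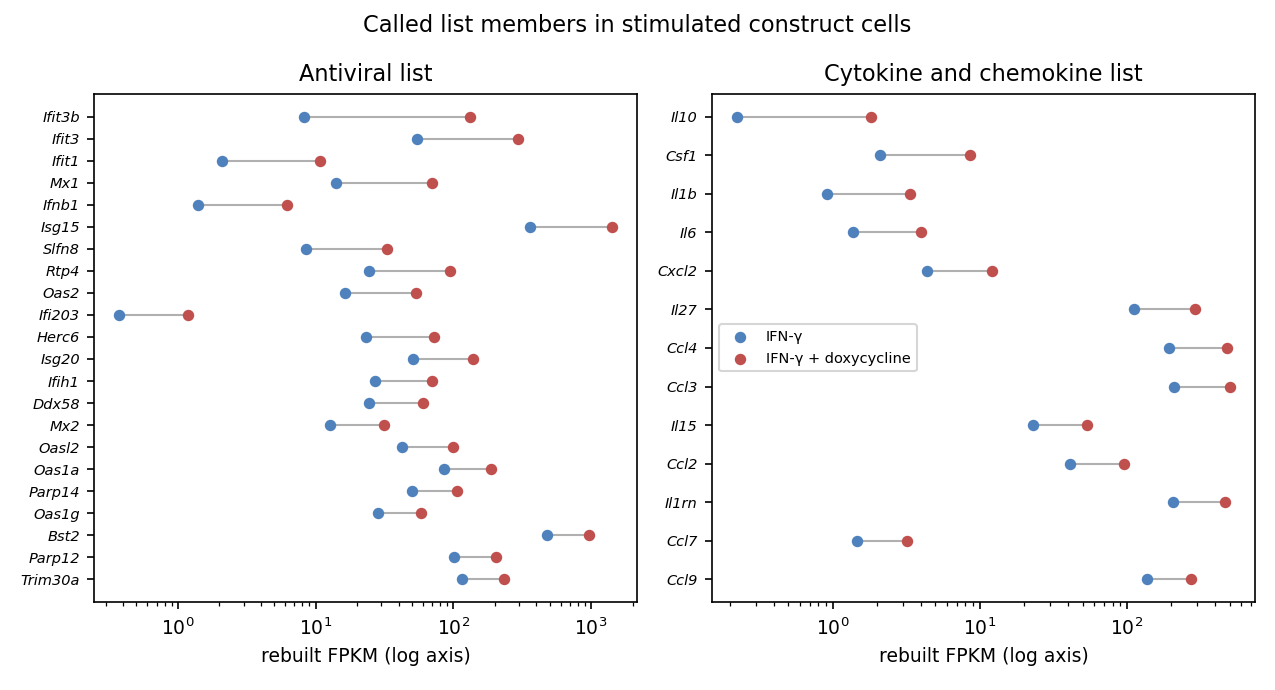
Rebuilt FPKM (log axis) of the called members of the antiviral list (left) and of the cytokine and chemokine list (right) in construct cells with interferon-gamma alone (blue) and with interferon-gamma and doxycycline (red), 1 authors' value per group without error. All 22 antiviral and all 13 cytokine genes lie higher with doxycycline, Isg15 at 1429 against 358.

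The other members of the 10 largest rises in stimulated cells were Trim30c, Ifit1bl1, Trim30b, Ms4a4c, Ifi214, Apol9b and Tgm2, the transglutaminase gene, which went from 10.5 to 74.6 rebuilt FPKM. S1pr1, Cldn11 and Igfbp4 were 12.1-fold, 11.6-fold and 9.17-fold lower than with interferon-gamma alone in the authors' deposited table, from levels of 1.07, 1.47 and 1.55 rebuilt FPKM. Haao, of tryptophan breakdown, the clock repressor gene Nr1d1, Cep68, Zfp775, Oit3, the proline synthesis gene Pycr1 and Efna1 were the other large falls. Among genes of interferon signalling, the Fc receptor genes Fcgr1 (87.5 to 274 rebuilt FPKM) and Fcgr4 (166 to 387) were higher and Ciita, the master regulator of MHC class II genes, was lower, from 2.88 to 1.14 rebuilt FPKM with a q of 0.015 in the authors' deposited table. A minor entry of Batf2 was also higher. Cd274 and Irf9 were not called and had small ratios, Cd274 with a log2 ratio of 0.20 and Irf9 with 0.30. Stat2 has no row for the group with both treatments, so its level there is not known. All 6 called pattern recognition genes were higher, led by Tlr3, a minor entry of Tlr7, Casp4 and Tlr9, and all 3 called NF-kB genes, Cd40, Traf1 and Bcl2a1a, but neither split passed the test (Fisher's exact test, two-sided, adjusted p = 0.078 and 0.417). Of the complement genes C3, C4b, Cfb and the receptor gene C3ar1 were higher and C1qb and C1qc were lower, and the test of this list is not given here. No parental group received interferon-gamma, so in stimulated cells doxycycline and CITED1 cannot be separated.

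The interferon-gamma responses with and without induction, which share no group, ran closely together. Of the genes called, 1156 were higher in both and 1082 lower in both, where lists drawn independently from the 5455 listed genes would share 473 and 453, and 6 were called in opposite directions. Across 2825 genes with a rebuilt level in all 4 construct groups, the log2 responses had a Pearson r of 0.95, a correlation across genes, which are not independent replicates and were listed because they changed. The response was larger with induction for 80.7% of the 1139 genes higher in both, with a median extra log2 change of 0.38, and for 75.3% of the 1070 genes lower in both, with a median of -0.28. The SD across genes was 1.88 without and 2.30 with induction. Whether the effect of induction on a gene differs with and without interferon-gamma could not be tested, because the table gives no standard error.

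**Figure D3:**
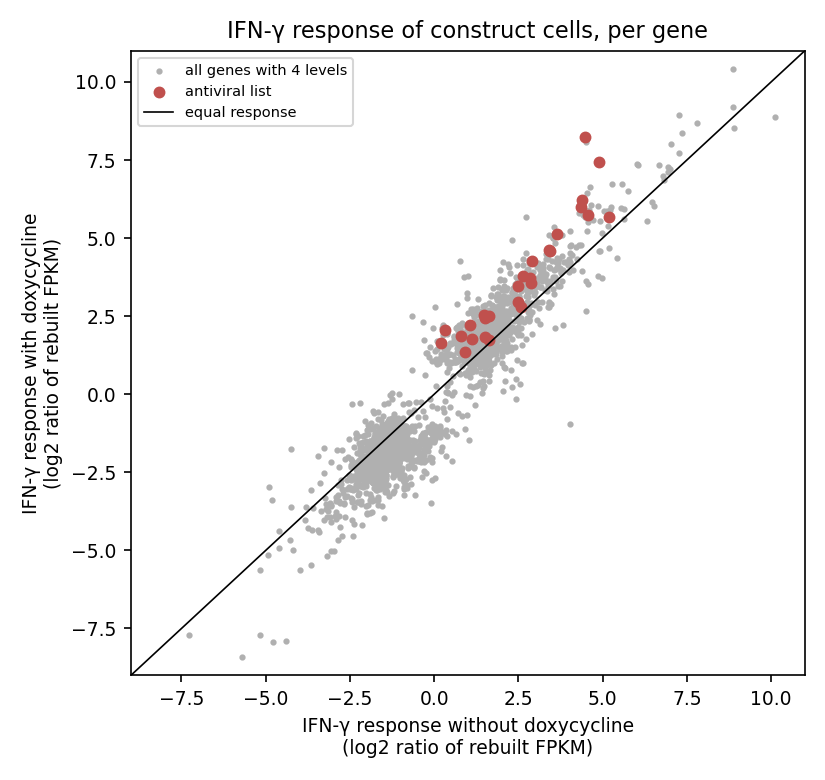
Log2 ratio of rebuilt FPKM with interferon-gamma over without, in construct cells without doxycycline (x axis) and with it (y axis), 1 point per gene for the 2825 genes with 4 rebuilt levels; red points are 27 genes of the antiviral list, and the line marks equal responses. Points spread further along the y axis than along the x axis (SD 2.30 against 1.88), and genes near 0 are few because the table lists only changed genes.

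Between the comparisons of CITED1 induction without and with interferon-gamma, 10 genes were called in both. Cited1, Pde1b, Pik3r6, Cd5l, Pla1a and Gm20634 were higher in both, where independent lists would share 0.752, and Padi2 and Soat2 were lower in both, against 0.698. Pde1b went from 8.55 to 32.2 rebuilt FPKM in stimulated cells. Cxcl2 and Vegfc were lower with induction in unstimulated cells and higher in stimulated cells. Several of these genes were named because the count was small, after their values were seen.

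Most markers of other cell types had no row. Of 17 fibroblast and epithelial markers 16 had no row, and of 16 lymphocyte markers 14 had none. This does not show that they were not expressed, since 13 of 25 macrophage identity genes and 12 of 15 housekeeping genes had no row either. Lck and Ighm, the lymphocyte markers that were called, were higher with interferon-gamma without and with doxycycline. Among macrophage identity genes the interferon-gamma responses went both ways, with Cx3cr1 and Cebpa lower and Aif1, Fcgr1 and Fcgr3 higher (Fisher's exact test, two-sided, adjusted p = 0.80 without and 0.879 with doxycycline). The 5 called dendritic cell markers, Clec9a, Xcr1, Itgax, Zbtb46 and Cd83, were higher with interferon-gamma alone (Fisher's exact test, two-sided, adjusted p = 0.137).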

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

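Of the tests below, those on doxycycline in construct cells, on shared pseudogene reads, on whole loci, on entries that fell, on scaling and on interferon-beta were chosen after the result was seen.

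Between the interferon-gamma responses without and with CITED1 induction, 6 genes were called in opposite directions: Acsf2, Fgd4, Fip1l1, Rab23, Synpo and Ttpal. Only Acsf2 was called on the same entry, with log2 ratios of 1.04 without and -1.47 with induction, and the difference was not tested. Between induction in unstimulated and in stimulated cells, 2 genes were called in opposite directions, and here too the difference was not tested. Cxcl2 had log2 ratios of -1.32 and 1.45, and Vegfc of -1.09 and 1.57. These genes were named after their values were seen.

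The response to interferon-gamma was larger with induction for most genes. A shift in scaling between libraries would move all genes one way, but the median extra log2 change was 0.376 for genes higher in both responses and -0.282 for genes lower in both. One common factor on the whole response is argued against as well: with the common slope taken off, the antiviral list's extra change lay at percentile 100 of 10000 matched random lists, and matched on response size its median of 1.03 again lay at percentile 100. A candidate explanation, examined after the result was seen, is a larger type I interferon signal. Ifnb1 was higher with both treatments by a log2 ratio of 2.14, which shows no direction of cause. As Ifnb1 is itself a member of the antiviral list and was already among its called rises, this is no independent test. Doxycycline itself stays open. In unstimulated parental cells the antiviral list had a median log2 ratio of -0.201 with doxycycline. Untreated parental cells are the baseline of that value, and untreated construct cells too lay below them, with a median of -0.37. No parental group received both treatments, so doxycycline and CITED1 cannot be told apart in stimulated cells.

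Pseudogene entries made up most calls with doxycycline in parental cells. In construct cells 12 of the 34 entries had levels, and their median log2 ratio with doxycycline was -0.020 (quartiles -0.12 and 0.12). This cannot decide on an effect of doxycycline, since an entry can have a construct level because it lay at least 2-fold below untreated parental cells. Over the 14 entries with levels in both untreated groups, the median log2 ratio of construct against parental cells was -1.28. Untreated parental libraries that stand apart may account for the pseudogene calls: they had the highest unstimulated level in 54.4% of 90 pseudogene entries against 26.8% of other entries. Without the called entries the share was 47.4% (exact 95% interval 36.0% to 59.1%). That set is not free of selection, since 28 pseudogene entries were also called lower in untreated construct than in untreated parental cells. Such entries can be listed because untreated parental levels were high. Sharing of reads with parent genes cannot be told apart from libraries that stand apart. That 81% of the entries called lower were pseudogenes restates the pattern, and of 20 parent genes 0 have both parental levels. No biological explanation other than doxycycline was tested.

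Many entries that changed strongly with interferon-gamma have no row for the group with both treatments. Of 1011 entries at least 4-fold apart between interferon-gamma and no treatment, 118 were missing there, 58 that rose (8.53% of those, with all entries of Stat2) and 60 that fell (18.1%). For entries that fell a level near zero, which would give an infinite fold, is a candidate explanation: their median lowest level was 0.442 rebuilt FPKM when missing against 1.18 with a row. For entries that rose this stays open, since their median lowest level was 4.26 rebuilt FPKM when missing (quartiles 0.835 and 9.81) against 0.987, but these levels are of other groups and the spreads overlap. Whole loci without a test result is another candidate explanation, as 52.9% of the 17 affected genes with several such entries lost all of them, against at most 22.2% in 1000 shuffles, and no biological explanation was tested.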

How the results depend on the processing

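The alternatives that leave out pseudogene entries or count entries in place of genes were chosen after the data were examined. No paired analysis was possible because the table gives no values per sample, and for the same reason the replicate block, leaving out replicates, a pseudocount of 0.1, adjustment within a comparison and the interaction tests with their alternatives were not run. Depth is unknown, so nothing can be said of what deeper sequencing would add. The minimum of 2-fold, and of 1.5-fold for lists, removed no gene, since the table was already filtered at 2-fold, and says nothing about stability.

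A q of 0.01 or less gave 25 in place of 49 genes for doxycycline in parental cells and 13 in place of 22 for CITED1 induction without interferon-gamma, which follows from the stricter limit. Without pseudogene entries the count for doxycycline in parental cells was 14. Apart from these, the counts of changed genes stayed within 1.5 times under the stricter q, the 1 FPKM minimum, the pseudocount of 1 with 1.5-fold, the rescaling, the omission of pseudogenes and the counting of entries. With the 1 FPKM minimum 17 of the 18 list results kept their side of the threshold. The osteoclast list in construct against parental cells with doxycycline did not (Fisher's exact test, adjusted p = 0.0791, against 0.0186 as reported and with the 1.5-fold minimum), as fewer members were tested. Rescaling changed the share of higher calls from 51.3% to 33.7% for interferon-gamma alone, from 49.8% to 28.0% for interferon-gamma with induction and from 51.9% to 45.6% for induction in stimulated cells. Genes that would newly pass after rescaling are not listed, so it mostly removes calls on one side. A pseudocount of 1 cannot change a direction, but of the fold changes named as largest rises or falls 106 stayed at 2-fold or more and 23 did not. The log2 ratio of Igf2bp1 went from -6.04 to -0.99 in untreated construct against parental cells, and that of S1pr1 from -3.60 to -0.93 between both stimulated groups.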

Other observations

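The lists in this part and their tests were planned, and only the choice of MHC class II and antiviral values in its last paragraph was made after the results were seen.

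Osteoclast-associated genes split in the interferon-gamma response. Ocstamp and Dcstamp, which act in the fusion of osteoclast precursors, were higher with interferon-gamma alone, from 0.382 to 42.2 and from 20.8 to 63.1 rebuilt FPKM. The protease gene Ctsk fell from 3.18 to 0.107 rebuilt FPKM, Acp5 from 2.43 to 0.690 and Nfatc1 from 8.48 to 2.5. The list had 2 members higher and 4 lower (Fisher's exact test, two-sided, adjusted p = 0.667), and 3 higher and 6 lower with induction (adjusted p = 0.705). In the stress list Atf3, Ddit3, Trib3 and Nupr1 were higher with interferon-gamma alone, while Phgdh and Shmt2 fell from 126 to 44.5 and from 117 to 41.4 rebuilt FPKM. Psat1, which like Phgdh acts in serine synthesis, was called higher with interferon-gamma under induction, from 2.70 to 30.6 rebuilt FPKM. It was not called with interferon-gamma alone, but its level was higher there too, at 21.01 against 2.77 rebuilt FPKM in untreated construct cells. The rise of Psat1 was thus not limited to cells with induction, and the difference between the responses was not tested. That list had 5 members higher and 2 lower (Fisher's exact test, two-sided, adjusted p = 0.667), and 6 higher and 4 lower with induction (adjusted p = 0.738). Phgdh was lower again with both treatments, at 17.2 against 44.6 rebuilt FPKM with interferon-gamma alone.

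Hypoxia and glycolysis genes had 5 members higher, such as Hif1a from 27.4 to 93.8 rebuilt FPKM and Vegfa from 10.1 to 28.1, and Mxi1 lower (Fisher's exact test, two-sided, adjusted p = 0.406). With induction 4 were higher and 2 lower (Fisher's exact test, adjusted p = 0.667). The list of Smad targets, whose test for interferon-gamma alone is not given here, split 3 to 3 with induction and 2 to 2 between both stimulated groups (Fisher's exact test, adjusted p = 1 each). M2-type genes had 4 members higher and 2 lower, Trem2 and Klf4 (Fisher's exact test, adjusted p = 0.80), 4 higher and 1 lower with induction (adjusted p = 0.406), and between both stimulated groups 2 higher and 1 lower (adjusted p = 1). Complement and Fc receptor genes had 6 members higher and 1 lower with interferon-gamma alone (Fisher's exact test, adjusted p = 0.251) and 8 higher and 2 lower with induction (adjusted p = 0.137). Reactive oxygen genes had 2 higher and 3 lower (Fisher's exact test, adjusted p = 0.80) and, with induction, 3 of each (adjusted p = 1). Lysosome genes had 3 higher and 0 lower (Fisher's exact test, adjusted p = 0.417) and, with induction, 2 of each (adjusted p = 1).

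MHC class II genes had few rows. H2-DMb2 was higher with interferon-gamma alone, from 0.287 to 10.5 rebuilt FPKM, and H2-DMa with interferon-gamma under induction, from 2.14 to 27.9. With interferon-gamma alone H2-DMa was at 37.3 rebuilt FPKM, and its level in untreated construct cells is not known. With both treatments H2-Ob, of the inhibitory chaperone H2-O, was at 0.586 rebuilt FPKM against 2.78 with interferon-gamma alone, beside the fall of Ciita. Cd74, the invariant chain gene, was 2.38-fold higher in construct than in parental cells with doxycycline in the authors' deposited table. The antiviral list showed small shifts in unstimulated cells: its median log2 ratio was 0.15 over 36 genes with doxycycline in construct cells, of which 29 were above 0 and 0 were called. In untreated construct against parental cells it was -0.37 over 36 genes, of which Slfn8 and Ifit3 were called lower. With doxycycline in both lines the median was 0.06 over 35 genes, of which 19 were above 0 (quartiles -0.22 and 0.24), so members went both ways. Doxycycline in parental cells gave -0.20 over 35 genes, of which 4 were above 0. The medians lay at percentiles 100, 0, 99.3 and 0 of random lists in this order, as a description of these groups, and were not tested. Those of -0.37 and -0.20 share untreated parental cells as their baseline, so they are not independent of each other.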
